A study of Mus musculus with 9 samples.

How the data were processed

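Genomic DNA of Lazy Piggy mouse medulloblastomas was sheared, joined to splinkerette adaptors and cut with BamHI before amplification from the SB part (IR libraries), the PB part (PB libraries) or their boundary (JX libraries), per the labels' protocols. The libraries were barcoded and sequenced in 9 lanes. The values used are raw counts per insertion position and library, as deposited by the authors, whole numbers of at least 1 with no scaling. The build is mm9, per the submitters' processing notes. The aligner, the counting rule, the gene annotation and any filter behind the deposited counts are not given in the sources used here. The table also lists for each position a gene, the part of the gene and the orientation relative to the gene, but no strand. A position outside gene bodies carries its assigned gene and a distance of up to 2355 kb. No gene was listed for 19.7% of lines and 18.5% of counts, and positions inside En2 held 7.07% of all counts.

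The arm, animal, library end, lane, donor chromosome and listed days of each library came from the authors' sample sheet with 868 lines, which names 141 animals or control DNAs. The animal was the replicate, so both ends and repeat lanes of an animal (7 animals were in 2 lanes) were summed per kind of library. An ID spelled with and without a leading zero was joined into 1 animal. Both spellings had the same highest IR site, their only shared called site (20% of the sites called in either), but 4 pairs of IDs in all had the same highest site, so the joining rests on the spelling. The sheet gave 2 animals conflicting arms, and these were put with the animals of no given arm. The comparison held 72 animals with tamoxifen and 47 without, and the 5 control tumours, the control DNAs and the 8 animals of no given arm were only described. The table separates no metastases or normal tissue of the animals compared.

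Positions within 10 bp were merged without regard to strand. A site was called in an animal and kind of library when it had at least 10 counts and at least 1% of the count of the highest site. A site called in several animals was credited to the animal in which it held the highest share. This gave 2311 called sites in IR, 6778 in JX and 2910 in PB. Positions were described as spread over animals where no animal held over 50% of the counts and at least 3 animals listed them, which covered 21 called IR sites, 3115 JX sites and 43 PB sites. A site was assigned to the gene that the table lists for it, in the body or outside. Counts outside the main chromosomes (0.0928%) were left out of chromosome and window counts. Windows and chromosome shares used the covered length, from position 1 to the highest position listed on each chromosome.

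Differences between arms per animal were tested with two-sided permutation tests of the mean with 100000 resamples, with Benjamini-Hochberg adjustment over the 3 kinds of library. An IR site counted as retained where the same animal had a JX count within 100 bp, and a PB site as away where it had no IR or JX count within 100 bp. Genes hit in at least 3 animals were tested between arms with two-sided Fisher's exact tests, adjusted over the genes of a library kind. Recurrence was tested in 100 kb windows with a one-sided exact Poisson-binomial test from each animal's number of sites, since gene lengths of mm9 were not at hand, with genes named from the table. The potassium channel list and 10 further lists were set against 10000 random lists of the same size, drawn without matching, and against lists matched in 10 classes on the number of positions below the site call. The lists covered the SHH pathway, human SHH medulloblastoma genes, mouse SHH model genes, chromatin regulators, granule neuron lineage, PI3K, RAS and growth signalling, cell cycle and DNA damage, other channels, long synaptic genes and 3 loci open to wrong mapping. Orientation was tested per named gene with at least 6 sites by a two-sided exact binomial test against an even split. The adjusted threshold was 0.05 throughout.

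The genes named were, per kind of library and arm, the 10 hit in the most animals, per kind of library the 8 with the lowest Fisher p, of each list up to 4 members hit in the most animals and in at least 3, and always Ptch1 and Kcnb2. Not every gene that this rule picks is given in the text. Further genes are named as chosen after their values were seen. Symbols are those of the table. Of 22353 symbols, 19886 were current in the given gene name table (assembly GRCm38.p6, used for names only), 2241 matched through 1 synonym and 226 did not match. In this table Odz4 is Tenm4 and Fam19a2 is Tafa2.

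The tests were tried on simulated data before use. With 200 genes planted at 30% of animals with tamoxifen against 2% without, Fisher's test recovered 99.5% in IR (1420 genes), 97.5% in JX (3659 genes) and 99% in PB (1751 genes), with 1 false call each. Planting 200 genes at once eases the adjustment, so recovery of a few genes was not measured. For the window test, 20 windows of 26427 were each planted in 20% of the animals of both arms pooled, with other sites spread uniformly. All 20 were recovered with 0 false calls in each kind of library. The real tests ran per arm, on unevenly spread sites and often on windows with fewer animals. The simulation therefore does not measure recovery or false calls under those conditions. With no difference between arms, the permutation test called 26 of 400 draws for IR sites (6.5%).

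Depth is given in the report per library end. The site call follows each library's highest site, so a shallow or highly clonal library can lose small sites, and 1 alternative thinned each animal to 1000000 IR, 200000 JX and 50000 PB counts. Alternatives fixed before the data were examined changed the share of the highest site (0.1% and 5%), the count minimum (2 and 50), the crediting of shared sites, the removal of chromosome 10, the depth, lanes as strata, the log2 scale, the distance (10 and 1000 bp), a minimum of 10 JX counts, genes within 10 kb, genes hit in at least 5 animals, windows of 25 and 250 kb and an adjusted p of 0.01. The software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.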

Results

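Transposon insertion sites were counted in SHH medulloblastomas of Lazy Piggy mice, which carry a mobile element built from Sleeping Beauty (SB) and piggyBac (PB) parts. A library called IR was amplified from the SB ends, a library called JX from the boundary of both parts, and a library called PB from the PB ends. The deposited table held 3961094 lines from 832 libraries, with 555006105 counts and 22353 gene symbols. The sequencing used 9 lanes, so the animal and not the lane was the replicate. The authors' sample sheet gave 72 animals with tamoxifen and 47 without, each with all 3 kinds of library. A further 5 control tumours, control DNAs and 8 animals with no usable arm label entered no comparison of arms. Median counts per library of the left SB end were 1668361 with tamoxifen and 1639563 without, and single libraries of both arms ranged from 145506 to 3340869. For the left JX end the medians were 287818 and 156069, and for the left PB end they were 165022 and 127816. The right PB end was shallowest, with medians of 18029 and 39532 and a range from 133 to 2063589. Counts without molecular identifiers are not independent molecules, so site calls rest on shares of a library and not on counting intervals. All coordinates are in mm9.

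The first comparison asked which loci carried insertions in more tumours than a uniform spread of sites gives, in each arm. The genes hit in the most animals in IR were the neighbours Otogl (27) and Ppp1r12a (26) on chromosome 10. Called IR sites in or next to Ppp1r12a, which encodes a targeting subunit of myosin phosphatase, were found in 18 of 72 tumours with tamoxifen (25%) and in 8 of 47 without (17.0%), between positions 107509595 and 107745451. Otogl, which encodes an otogelin-like protein of the inner ear, was hit in 16 tumours with tamoxifen (22.2%) and 11 without (23.4%). Nav3 was hit in 9 and 2, Pawr in 8 and 1, Ppfia2 in 8 and 1, and Syt1, which encodes a calcium sensor of synaptic vesicles, in 6 and 4. On chromosome 7, Fam168a was hit in 5 and 1, Plekhb1 in 6 and 0, and Rab6a in 3 and 2.

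Recurrence was tested in windows of 100 kb with a one-sided exact Poisson-binomial test and Benjamini-Hochberg adjustment over 26427 windows. The lead window with tamoxifen lay in Ppp1r12a, at 107600001 to 107700000 of chromosome 10. It held called IR sites in 11 animals (adjusted p 1.14e-18) and called PB sites in 14 (adjusted p 1.21e-24). In JX the lead window lay in Otogl, at 107400001 to 107500000, with 12 animals with tamoxifen (adjusted p 6.63e-16) and 9 without (adjusted p 3.61e-12). The tamoxifen arm had 22 windows past an adjusted p of 0.05 in IR, 18 in JX and 18 in PB, and the untreated arm had 8, 10 and 7. Both arms shared 7 of these windows in IR, 7 in JX and 5 in PB. The larger number of animals in the tamoxifen arm raises its number of windows, so these counts are no comparison of arms.

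Most recurrent windows lay on the chromosome that the sample sheet lists as the donor of the transposon, chromosome 10 in 90 animals and chromosome 7 in 29. In IR with tamoxifen 15 of the 22 windows were on chromosome 10 and 3 on chromosome 7, and all 8 windows of the untreated arm were on chromosome 10. All 26 animals with a called IR site in Ppp1r12a and 26 of the 27 with one in Otogl had chromosome 10 as donor. The remaining 4 IR windows lay in En2 on chromosome 5, Sfi1 on chromosome 11, and Klf6 and Zfp934 on chromosome 13. With the donor chromosome of each animal left out, the window of En2 alone passed in IR with tamoxifen (5 animals, adjusted p 2.33e-05) and none passed in untreated animals, where 532 windows had an unadjusted p under 0.05 in this test. The same En2 window passed in JX with tamoxifen (5 animals, adjusted p 0.00823). In JX without tamoxifen a window in Ctnna2 on chromosome 6 and one with no listed gene on chromosome 13, at 68100001 to 68200000, passed with 4 animals each (adjusted p 0.0165). Of the 4 animals of the Ctnna2 window, 2 had their sites at positions with counts spread over at least 3 animals. Of the 7 called IR sites in En2, 6 lay at positions with counts spread over at least 3 animals, between 28496384 and 28496775. Klf6, Zfp934 and the windows without a gene were picked after their values were seen.

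**Figure D1:**
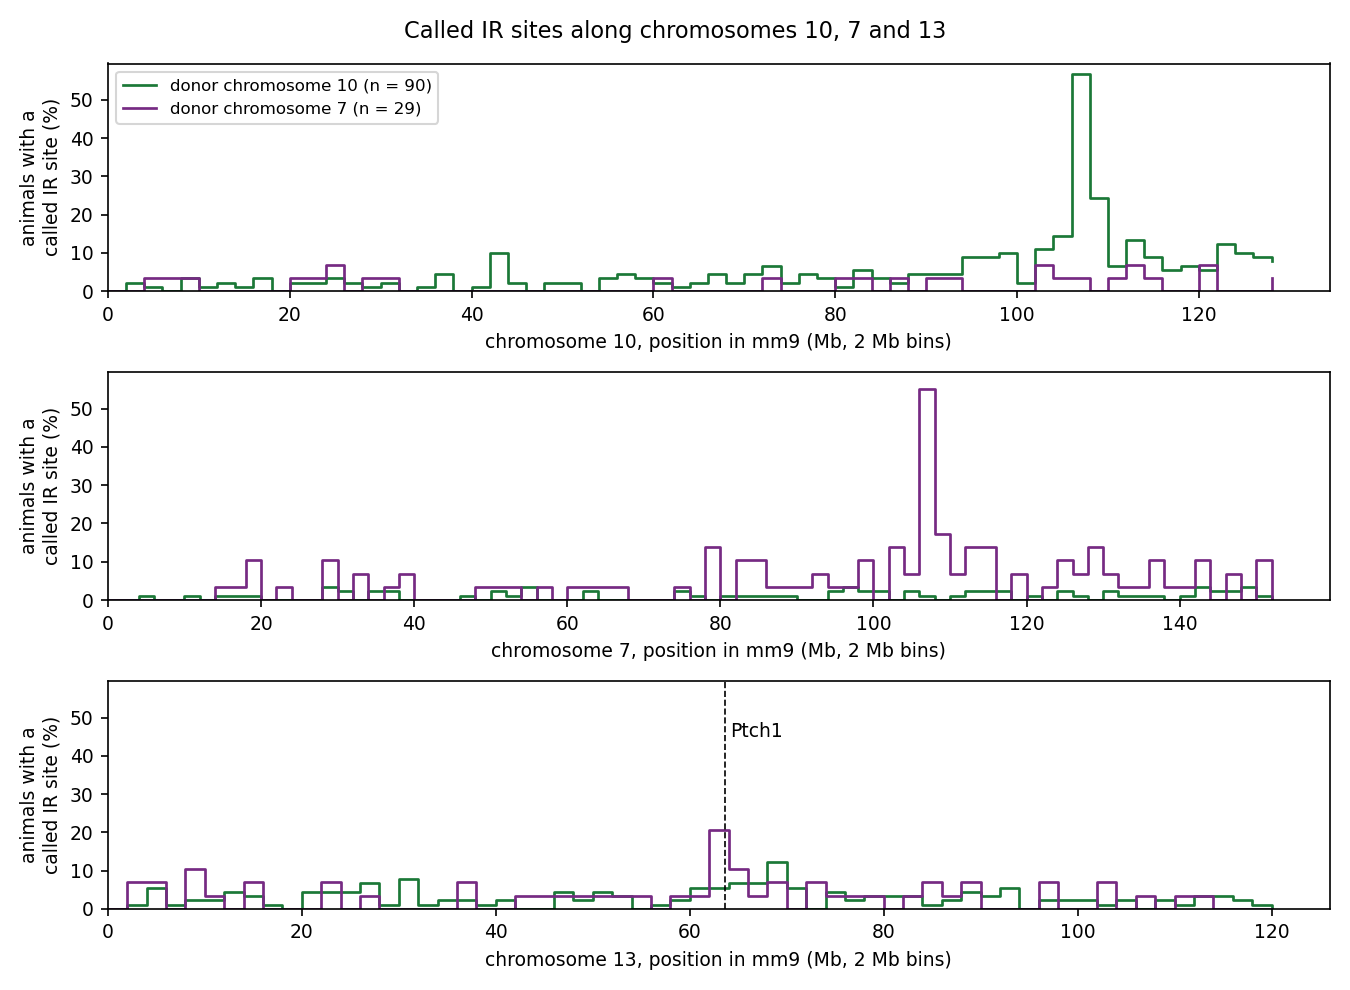
Percent of animals with a called IR site in bins of 2 Mb along chromosomes 10, 7 and 13 (horizontal axes in Mb of mm9), for 90 animals with donor chromosome 10 and 29 with donor chromosome 7. The lines rise near 107 Mb only in animals whose donor is the chromosome drawn, and the dashed line marks Ptch1 on chromosome 13.

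The second comparison asked which genes were hit at a different frequency with and without tamoxifen, the question of maintenance drivers that the series states. Among genes hit more often with tamoxifen, Ppfia2 had called PB sites in 8 of 72 animals and 0 of 47, and Prkg1, which encodes a cGMP-dependent protein kinase, had called JX sites in 7 and 0. In the other direction, Mctp1 had called JX sites in 0 and 4 animals, and Alx4, a homeobox gene, had called IR sites in 0 and 3. Plekhb1 had called IR sites in 6 animals and 0, Pcdh15 in 5 and 0, and Ptprr in 4 and 0. Ppp1r12a differed most in PB, with 22 animals (30.6%) against 7 (14.9%). Not all of these genes leaned the same way in every kind of library, since Ppp1r12a had called JX sites in 14 animals (19.4%) and 12 (25.5%). Ppfia2 was hit more often with tamoxifen in all 3 kinds, with 8 of 72 animals and 1 of 47 in IR. In JX it was hit in 9 and 3 (Fisher's exact test, p 0.360).

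No gene passed an adjusted p of 0.05 in Fisher's exact test (two-sided, Benjamini-Hochberg over genes hit in at least 3 animals), with 40 genes tested in IR, 244 in JX and 55 in PB. At an unadjusted p under 0.05 the test gave 0 genes in IR, 2 in JX and 1 in PB. The lowest p values were 0.0592 for Alx4 in IR (adjusted 0.739), 0.0225 for Mctp1 in JX (adjusted 1), 0.0412 for Prkg1 in JX (adjusted 1) and 0.0214 for Ppfia2 in PB (adjusted 0.846). Of the 7 called JX sites in Prkg1, 4 lay at positions with counts spread over at least 3 animals. Simulated genes hit in 30% against 2% of animals were called in 99.5% of cases in IR, and smaller differences were not simulated.

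**Figure D2:**
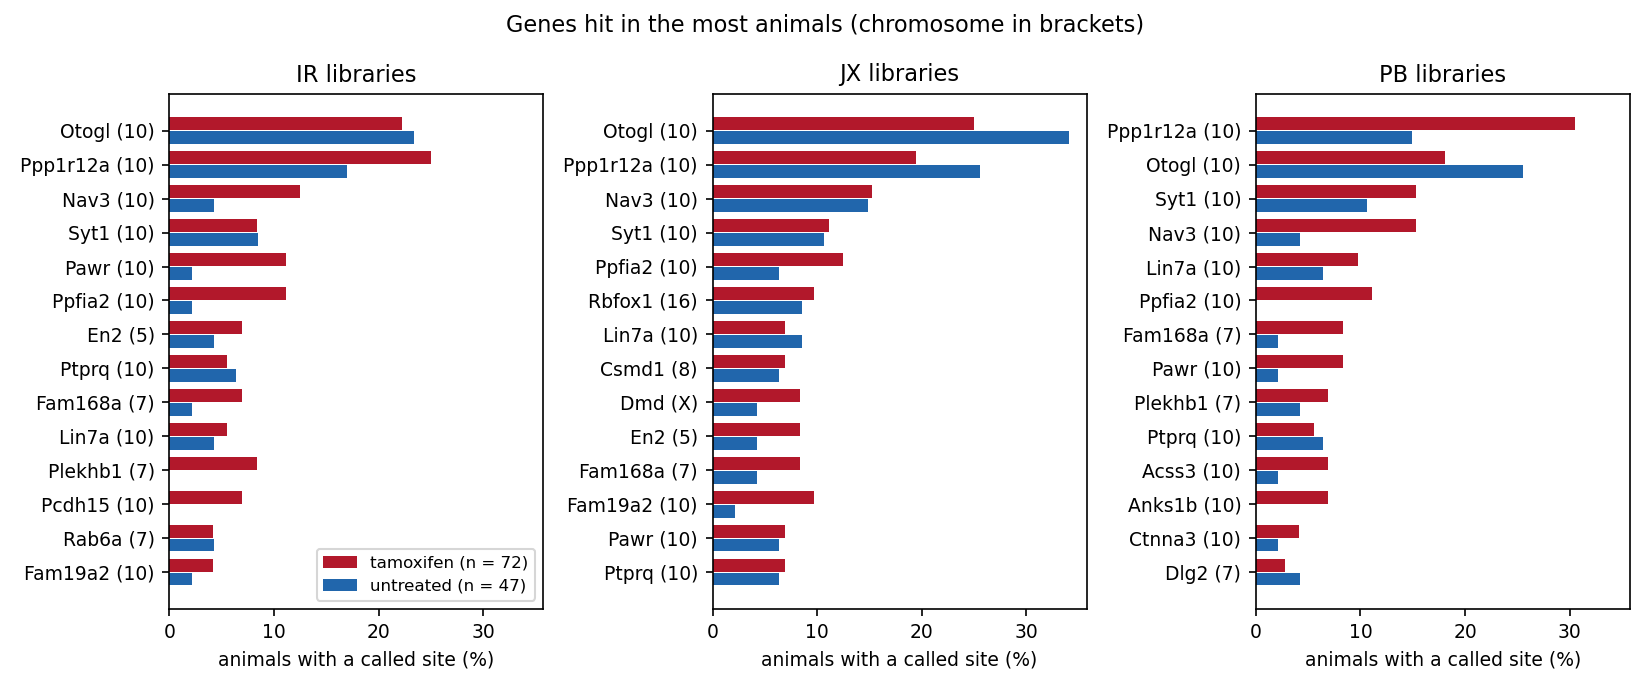
Percent of animals with a called site in or next to a gene, for the named genes hit in the most animals in each kind of library (72 animals with tamoxifen and 47 untreated, chromosome in brackets). Genes of chromosome 10 fill most places in IR and PB, and both arms are hit in most genes drawn.

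The series title names potassium channels, so the 95 symbols of the Kcn family in the table were followed as a fixed list. Kcnb2, which encodes a voltage-gated channel subunit, had no called IR or PB site in any of the 119 animals. Its single called JX site, in an intron at position 15541972 of chromosome 1, was found in 1 animal with tamoxifen with 0.0246% of that animal's JX counts. That position had counts spread over at least 3 animals. The most often hit members were Kcnk13 and Kcnq5, each with called JX sites in 2 animals with tamoxifen and 1 without. Of the 3 JX sites of each gene, 2 lay at positions with counts spread over at least 3 animals. Kcnk13 had no called IR or PB site, and Kcnq5 had 1 animal in each of these, at 21966334 and 21966259 of chromosome 1. At least 1 animal had a called site in 12 Kcn genes in IR, 24 in JX and 16 in PB.

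Called sites in Kcn genes averaged 0.139 ± 0.484 (SD, n = 72) per animal with tamoxifen and 0.0638 ± 0.247 (SD, n = 47) without in IR. For JX the means were 0.361 ± 0.877 and 0.191 ± 0.495, and for PB 0.264 ± 0.750 and 0.0638 ± 0.247, with the same numbers of animals. Two-sided permutation tests gave p values of 0.392, 0.271 and 0.0886, and the lowest adjusted p was 0.266 in PB. Fisher's exact test covered 0 Kcn genes in IR, 2 in JX (Kcnk13 and Kcnq5) and 0 in PB, and 0 had an unadjusted p under 0.05. A gene hit in 3 animals cannot fall below p 0.0592 with these arms, so no single Kcn gene could have passed. A Kcn gene was hit in a mean of 0.126 animals in IR, 0.358 in JX and 0.211 in PB. Against 10000 random lists of 95 genes, as a description without matching, p was 0.202, 0.0766 and 0.0464, and against lists matched on positions below the site call it was 0.931, 1 and 0.745. How the study chose this gene family is not given in the sources used here.

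Other fixed lists held genes of known pathways. Gli3, a transcription factor of the SHH pathway, had called JX sites in 2 animals of each arm and called IR sites in 1 of each, and its highest site took 43.9% of an animal's IR counts in an intron at 15669141 of chromosome 13. Ptch1, whose product restrains the SHH pathway, had 1 called IR site, in an intron at 63617312 of chromosome 13 in an untreated animal, with 0.142% of that animal's IR counts and no called JX or PB site. Pdgfra had called JX sites in 3 animals with tamoxifen and 1 without, Tcf4 in 2 and 1, Erbb4 in 3 and 1, and Tet2 in 1 and 2. Cntn1 had called JX sites in 4 and 0 animals. Positions with counts spread over at least 3 animals held 3 of the 4 JX sites of Cntn1, 3 of 4 of Pdgfra and 2 of 4 of Erbb4. They also held 2 of 3 of Tet2 and 1 of 3 of Tcf4, and 3 of the Pdgfra sites lay downstream of the gene.

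None of the lists held a gene past an adjusted p of 0.05 in Fisher's exact test, over all genes or adjusted over the list alone, but only 0 to 3 members of a list were tested in IR, 0 to 16 in JX and 0 to 2 in PB. Members hit in under 3 animals were not tested, and those hit in 3 cannot reach p 0.05. The list of synaptic adhesion and very long genes held the only member at an unadjusted p under 0.05, Prkg1 in JX. Animals with a hit in the list of mouse SHH model genes made up 19.4% with tamoxifen and 4.26% without in JX (Fisher's exact test, p 0.0256, adjusted over 11 lists 0.281), 8.33% and 2.13% in IR (p 0.242) and 4.17% and 4.26% in PB (p 1). Mean animals per member in JX were compared with random lists matched on positions below the site call. The means were 0.409 against 0.358 for the SHH pathway (p 0.725), 0.552 against 0.455 for human SHH medulloblastoma genes (p 0.510) and 0.90 against 0.49 for mouse SHH model genes (p 0.0880). Chromatin regulators had 0.673 against 0.486 (p 0.178), granule neuron lineage genes 0.667 against 0.577 (p 0.603), and PI3K, RAS and growth signalling genes 0.926 against 0.465 (p 0.0414, adjusted 0.152). Cell cycle and DNA damage genes had 0.174 against 0.243 (p 0.766), and channels other than potassium channels 0.470 against 0.418 (p 0.454). The list of synaptic adhesion and very long genes, such as Csmd1, Dmd and Cntnap2, averaged 3.36 animals against 0.970 (p 0.0004, adjusted 0.0044). Once positions spread over animals were removed, it averaged 1.79 against 0.639 (p 0.0248, adjusted 0.136). The same list did not pass in IR, with 0.75 against 0.391 (p 0.0900, adjusted 0.387), or in PB, with 1.18 against 0.480 (p 0.0508, adjusted 0.279). This list includes genes chosen for their length, and random lists were matched in classes of positions below the site call, not on length. Within a class, very long genes can be hit more often for their length alone. The excess of this list in JX therefore does not tell gene length from other causes. In JX, En2, Foxf2 and Sfi1, listed beforehand as loci open to wrong mapping, averaged 5.67 against 0.508 (p 0.0032, adjusted 0.0176). Once positions spread over animals were removed, they averaged 2.33 against 0.313 (p 0.0132, adjusted 0.136). With the same removal, mouse SHH model genes had 0.50 against 0.304 (p 0.225). PI3K, RAS and growth signalling genes then had 0.556 against 0.291 (p 0.0928). The percentages of animals with a hit in a list were not recounted without those positions.

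Whether tamoxifen changed the number, clonality or composition of insertions was asked per animal. Called IR sites numbered 21.4 ± 41.5 (SD, n = 72) per animal with tamoxifen and 16.4 ± 14.9 (SD, n = 47) without. The JX libraries gave 60.9 ± 107 and 51 ± 66.7 sites, and the PB libraries 27.8 ± 40.5 and 19.3 ± 14.9. The highest IR site took 26.3% ± 15.1 of counts with tamoxifen and 27.6% ± 14.9 without, the highest JX site 20.1% ± 16.9 and 18.7% ± 17.9, and the highest PB site 36.7% ± 19 and 33.9% ± 16.3. The highest site lay in Ppp1r12a in 5 of 119 animals in IR and 3 in PB.

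Two-sided permutation tests with 100000 resamples gave p values of 0.545, 0.594 and 0.171 for the number of sites and 0.647, 0.656 and 0.410 for the share of the highest site, in IR, JX and PB. Each of these differences was smaller than the SD between animals, which alone does not exclude a difference of means. The mean number of IR sites leaned on 1 animal with 334 sites, and without it the tamoxifen arm had 17.0 ± 18.3 (n = 71). The JX mean with tamoxifen likewise fell to 52.0 ± 77.0 without its animal with the most sites. Medians were lower with tamoxifen than without, 12 and 13 in IR, 21 and 25 in JX, and 11 and 15 in PB. Within lanes, IR sites were more numerous with tamoxifen in 4 of 9 lanes, JX sites in 3 and PB sites in 5.

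The JX libraries read elements whose PB part is still joined to the SB part, so the share of IR sites with JX counts was compared between the arms. Of called IR sites, 96.1% ± 13.5 (SD, n = 72) with tamoxifen and 97.4% ± 6.98 (SD, n = 47) without had a JX count within 100 bp in the same animal, a share that depended on the site call (60.4% and 65.4% at 0.1% of the highest site). Every called IR site had one in 93 of 119 animals. The lowest animal with tamoxifen had a share of 4.49% and the next 47.3%, and the lowest without had 66.7%. The mean and SD with tamoxifen thus leaned on the lowest animal. JX counts of another animal of the same lane matched 39.1% ± 19.2 of IR sites (n = 119), and 10.9% ± 10.3 when at least 10 JX counts were asked for. With that stricter rule the animals' own JX libraries matched 94.2% ± 15.4 and 96.0% ± 8.58. Called PB sites with no IR or JX count within 100 bp made up 34.7% ± 24.0 with tamoxifen and 34.1% ± 21.8 without. This share depended on the distance, with 98.0% and 95.5% at 10 bp and 14.3% and 14.2% at 1000 bp.

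The permutation test gave p 0.590 for the share of IR sites with JX counts. For the share of PB sites away from IR and JX sites it gave p 0.903, so neither difference of means passed the threshold. The first share was higher with tamoxifen in 4 of 9 lanes and the second in 5. In the 71 animals with tamoxifen and a number of days listed (4 to 249, median 49, of treatment or to the end point, which the sheet does not say), the share of IR sites with JX counts followed the days with Pearson's r 0.0189 (permutation p 0.865) and Spearman's rho 0.0856 (permutation p 0.479). Pearson's r was -0.0161 without the 2 animals farthest from the median, and it was positive in 3 of the 5 lanes with at least 6 animals in which the share varied. This was 1 of 5 relations with days, and none passed after adjustment (lowest adjusted p 0.192).

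**Figure D3:**
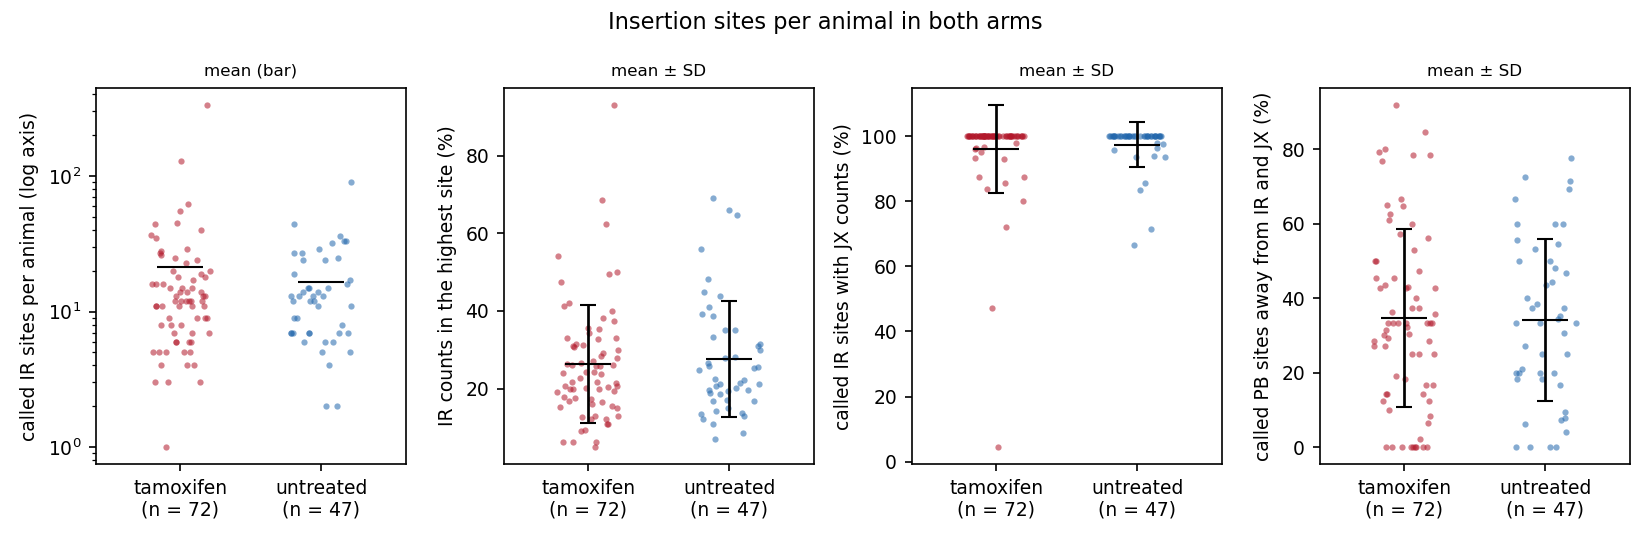
Each point is an animal (72 with tamoxifen, 47 untreated), with the number of called IR sites on a log axis, the percent of IR counts in the highest site, the percent of called IR sites with JX counts, and the percent of called PB sites away from IR and JX. Bars give the mean, with the SD in the last 3 panels, and the arms overlap in each panel.

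Insertions were unevenly spread over chromosomes and gene parts. Chromosome 10 held 20.2% of called IR sites for 4.92% of the covered length, a fold of 4.10, and its fold was 2.78 in JX and 4.43 in PB. In animals with donor chromosome 10, 29.2% ± 18.3 (SD, n = 90) of IR sites lay on chromosome 10, against 5.03% ± 11 (SD, n = 29) in animals with donor chromosome 7. Chromosome 7 held 24.4% ± 15.3 of IR sites in the latter and 5.29% ± 9.03 in the former. Chromosome 13, no donor in any animal compared, came second in IR with a fold of 2.29, and the X chromosome was lowest among those with sites, with a fold of 0.282. Introns held 47.4% of called IR sites with tamoxifen and 45.8% without, and exons held 2.92% and 2.59%.

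Orientation relative to the gene was near even over all gene bodies, with 48.9% of IR sites in the gene's own direction with tamoxifen (exact binomial test, p 0.565) and 52.8% without (p 0.3). Syt1 was the 1 gene of 13 tested in IR with a skew past adjustment, with 1 site in its own direction and 12 opposite (exact binomial test, p 0.00342, adjusted 0.0444). Called PB sites within 1000 bp of a called IR site of the same animal and gene were listed in the direction opposite to it in 1062 of 1087 cases (97.7%), so directions in PB read the other way round. Syt1 had 19 PB sites in its own direction and 8 opposite, which leaned the same way as IR without passing (p 0.0522, adjusted 0.313), and 12 and 18 in JX (p 0.362). Several of these sites can come from 1 animal, so they are not all independent.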

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

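Dixon's test was set before the values were seen, the search for animals that share sites was chosen after the sample sheet had been read, and no explanation of what they picked out was tested.

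Among the 5 control tumours, 1 had 526 called IR sites and the next 31, a gap larger than Dixon's test allows for 5 values (0.941 against a limit of 0.71). That tumour had the shallowest SB libraries of the group, with 120227 and 133021 counts. The share of counts in the highest IR site was 34.7% in 1 control tumour and 9.50% in the next, which also passed Dixon's limit (0.803). These were 2 of 7 measures tried in this group, and chance passes about 1 of 20. The remaining 5 measures stayed within the limit, with 24 to 175 called JX sites and 1 to 26 called PB sites per control tumour. What sets these control tumours apart from the tumours compared is not given in the sources used here.

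An animal with no usable arm label shared 12 called IR sites with an untreated animal of another lane, 92.3% of the sites called in either. A second pair, an animal with no usable arm label and one with tamoxifen in another lane, shared 11 sites, or 61.1%. The median over all 9453 pairs of IDs was 0 shared sites, and the next pair in order shared 25% of its sites. En2 and Foxf2 were left out of this count. Sites of the 119 animals compared were called and credited among those animals alone, so these pairs move no called site of the arms.

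A difference of the arms between animals with donor chromosome 10 and donor chromosome 7 was tested for the 8 measures per animal by permutation with 20000 resamples, and none passed (lowest adjusted p 0.560).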

How the results depend on the processing

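Chosen only after seeing the data were the tests with each animal's donor chromosome left out, without En2, Foxf2 and Sfi1, without positions spread over animals or listed in over 10% of animals, without the animal with the most sites, on gene bodies alone, and against positions below the site call. The cause of the changes given here was not tested unless one is stated.

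Of 280 values under alternatives, 204 kept their direction and their side of the threshold, or stayed within 1.5 times the count reported. Fisher's exact test gave 0 genes past an adjusted p of 0.05 in all 48 repeats (lowest adjusted p 0.301), with 0 to 17 genes at an unadjusted p under 0.05 in IR, 0 to 40 in JX and 0 to 13 in PB. All 100 splits of the animals into arms of the same sizes gave at least the real count of 0 genes in each kind of library, as any split must, so the splits decide nothing (highest other split 0 in IR, 0 in JX and 1 in PB). No test of a value per animal passed under any alternative (lowest adjusted p 0.141).

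The sign of the difference between arms turned in 14 of those values, all far from the threshold. Called JX sites (tamoxifen minus untreated) gave -2.76 at 0.1% of the highest site, -16.1 with sites counted in every animal, -0.159 without En2, Foxf2 and Sfi1, and -0.0781 on the log2 scale. Called IR sites gave -0.823 and PB sites -0.582 at 5% of the highest site, and PB sites gave -0.0880 on the log2 scale. The share of PB sites away from IR and JX sites gave -3.07 at 0.1%, -0.450 at 5%, -0.0912 at 50 counts, -0.245 with sites counted in every animal and -2.02 at fixed depth, all in percentage points. The share of IR sites with JX counts gave 0.585 at fixed depth, and the share of the highest JX site -1.03 with lanes as strata. Without the animal with the most sites the JX difference was 1.07 in place of 9.92 and the IR difference 0.582 in place of 4.98. The IR difference rose to 150 at 0.1% of the highest site (permutation test, p 0.0727), 112 without positions listed in over 10% of animals (p 0.149), 25.3 without En2, Foxf2 and Sfi1 and 24.3 without positions spread over animals, the last 2 with medians unchanged, and fell to 0.616 at fixed depth. The PB difference, 8.59 as reported, was 81.0 at 0.1%, 25.4, 24.3 and 22.9 under those filters in the same order, and 3.23 at 50 counts. None of these passed the threshold. The share of IR sites with JX counts fell to 60.4% with tamoxifen and 65.4% without at 0.1% of the highest site, and to 64.7% and 72.8% without positions listed in over 10% of animals.

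Many counts of recurrent windows moved. At 0.1% of the highest site, IR had 146 windows with tamoxifen and 26 without, JX 69 and 19, and PB 98 and 23. At 5%, with fewer sites, these counts were 7 and 5, 10 and 4, and 4 and 1. With sites counted in every animal, JX had 870 and 780, since 1 site then counts in many animals. Without chromosome 10, IR had 4 and 0, JX 3 and 3, and PB 2 and 0. With each animal's donor chromosome left out, IR had 1 and 0, JX 1 and 2, and PB 0 and 0. Per gene against positions below the site call, with donor chromosomes left out as well, IR had 1 and 0, JX 1 and 0, and PB 0 and 0. Where a count was 0, the Poisson-binomial test gave 173 to 648 windows, or 205 to 257 genes, at an unadjusted p under 0.05. Where sites are few, a site in 1 animal can be enough for such a p, so these do not count recurrent loci.

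Windows of 25 kb gave 11 and 3 in IR and 4 without tamoxifen in PB. Windows of 250 kb gave, without tamoxifen, 3 in IR, 6 in JX and 4 in PB. At an adjusted p of 0.01, IR had 12 and 3 and PB without tamoxifen 3. With tamoxifen, IR had 14 windows without En2, Foxf2 and Sfi1 and 14 without positions spread over animals, with mean sites per animal at 42.1 and 41.1 in place of 21.4 but the median at 12 as before. Without positions listed in over 10% of animals, IR had 96 and 20 and JX 51 and 21. That filter also removed the highest called IR site of 108 of 119 animals, so lower sites passed the 1% rule.

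Mean animals per potassium channel gene passed an unadjusted p of 0.05 against unmatched lists at 0.1% of the highest site in IR (1.21) and JX (1.95). In JX it also passed without chromosome 10 (0.337), with each animal's donor chromosome left out (0.337), without En2, Foxf2 and Sfi1 (0.411) and without positions listed in over 10% of animals (0.611), where IR passed as well (1.06). In PB it no longer passed at 5% (0.0632), at 50 counts (0.158), with sites counted in every animal (0.211), at fixed depth (0.105) or for gene bodies alone (0.126). Against lists matched on positions below the site call, the means (0.126 in IR, 0.358 in JX, 0.211 in PB) lay at percentiles 37.5, 48.7 and 62.8, so the side of the random mean turned in IR and JX and the PB call ended.

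Not run were all samples of an animal and leave-one-out (only primary tumours were given and both arms exceeded 5 animals), TA and TTAA sites as background (no mm9 genome), and lanes as strata for windows and lists. Lists matched on gene length could not be drawn without mm9 gene lengths, so unmatched lists were the reported ones. No paired analysis was possible because the arms hold different animals. Depth limits the shallow PB libraries most, since 92 of 119 animals reached the fixed depth in PB against 116 in IR and 113 in JX.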

Other observations

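Tests chosen only after the result was seen were local hopping and selection for the recurrent windows, local hopping and linkage to Ptch1 for chromosome 13, and the distance filter for PB sites.

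Chromosome 13, which carries Ptch1, held 14.2% ± 12.7 of called IR sites per animal (SD, n = 119) for 4.55% of the covered length. A permutation test that flips the signs of the deviations from that share gave p 1e-05, the smallest it can give. It assumes deviations that are symmetric without an excess. A called IR site lay there in 94 animals and 86 were above the share, but in animals with few sites 1 site is enough for that. The arms had 15.1% ± 13.4 with tamoxifen and 12.8% ± 11.8 without (permutation test, p 0.354). With each animal's donor chromosome left out, the 10 Mb bin from 60000001 to 70000000, which holds Ptch1, had called IR sites in 40 animals, 26 with tamoxifen and 14 without, against 20 in the next bin and a median of 5 over 265 bins. The bins ranked 2 to 6 also lay on chromosome 13, with 15 to 20 animals, so the excess was not confined to the bin that holds Ptch1. In the bin of Ptch1, sites lay in or next to Zfp934 in 4 animals and BC048507 and 4932441B19Rik in 3 each. They lay in Ptch1 itself in 1 animal, and no gene of the bin gathered them. The first 3 of these genes were picked after their values were seen.

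Among the explanations, local hopping from the donor is argued against by the folds over length on chromosome 13, 2.51 in animals with donor chromosome 7 and 2.21 in those with donor chromosome 10. A mapping or target bias stays open, since IR positions below 10 counts found in 1 animal were also enriched on the chromosome, 1.22-fold. This lay just over the bound of 1.2 that would have spoken against such a bias. In JX and PB, for which no bound was set, such positions had folds of 1.13 and 1.09, against 1.44 and 1.66 for called sites. The bin of Ptch1 held 0.646% of the IR positions and 2.47% of called IR sites for 0.379% of the length. With donor chromosomes left out, the bin ranked first both in these positions (0.744%) and in its share of called sites over its share of them (4.43), so such a bias could add to the count but was not separated from other causes. A candidate explanation is selection for sites linked to Ptch1, whose bin ranked first of all bins with 40 animals. That rank had been seen when the explanation was chosen, and the repeats given below use the same animals, so neither is independent support. The bins ranked 2 to 6 lay elsewhere on chromosome 13, so the excess ran beyond the bin of Ptch1. The bin stayed first at 5% of the highest site (28 animals, next 15), at 0.1% (65, next 51), without shared sites (39, next 18) and without positions spread over animals (40, next 21), but Ptch1 genotypes are not given in the sources used here, so linkage remains a hypothesis.

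Recurrent windows around Ppp1r12a, Otogl, Nav3 and Syt1 on chromosome 10 followed the listed donor chromosome. The mean share of called IR sites on chromosome 10 was 5.79 times higher in animals with donor chromosome 10 than in those with donor chromosome 7, as local hopping from the donor would give. Selection for insertions in these genes would raise them whatever the donor, whereas few animals with donor chromosome 7 were hit there. To keep the animals apart from the choice of windows, each was looked up in the chromosome 10 windows called in the other arm (15 with tamoxifen, 8 without), and 1 of 29 with donor chromosome 7 (3.45%) and 47 of 90 with donor chromosome 10 (52.2%) had a called IR site there, a ratio of 0.0660 that argues against selection alone (Fisher's exact test, p 6.45e-07). Selection acting on single genes on top of local hopping may still be present and was not tested apart.

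Of the 6778 called JX sites, 3115 lay at positions spread over animals, in genes such as Dmd, Rbfox1 and Kcnb2. Of these, 94.4% were also listed in JX libraries of control DNA, against 7.34% of the other called JX sites. The listing in control DNA argues against insertions that arose separately in each tumour as the source of most of them, though what the control DNAs are is not given. Annealing of the primer without a transposon could give such sites. Of them, 52.6% had an IR count within 100 bp in the same animal (77.0% of the others), between the bounds set for and against annealing. No background from IR counts of other animals was taken, so this share does not tell annealing from other sources of shared positions. No biological explanation was tested.

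The listed days were read as days of tamoxifen, though the sample sheet does not say whether they count treatment or time to the end point. If longer tamoxifen removed the PB part, the share of IR sites with JX counts would fall with them, and Spearman's rho was 0.0856 in 71 animals with tamoxifen (permutation test, p 0.479). Every called IR site had JX counts in 56 of these 71 animals, so the measure was at its ceiling under this site call, which was looked at after the result was seen, and an effect of the days and none cannot be told apart.

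If PB elements that moved were less bound to the donor chromosome, PB sites more than 1000 bp from any IR or JX count would lie there less often than IR sites. They did so in 13.5% ± 24.1 of sites per animal against 27.2% ± 17.0 for IR sites (n = 68), a difference of -13.8 percentage points (permutation test, p 0.00024), lower in 51 animals and higher in 12. The distance filter itself removes more sites on the donor chromosome, since IR sites of animals of other lanes with the same donor went from 25.5% ± 1.42 there to 23.0% ± 2.17 when passed through it. It is argued against as the whole cause, because the away PB sites still differed from these filtered sites by -9.47 percentage points (permutation test, p 0.00214). Reintegration may explain the rest, but the share was low in both arms, 12.4% ± 16.8 with tamoxifen and 14.6% ± 30 without (n = 34 each), and wrongly mapped PB positions were not tested.

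Other values belong to no comparison. An animal with conflicting arm labels had 389 called IR sites, of which 0.771% had JX counts, and 98.9% of its 349 called PB sites lay away from IR and JX. Its SB libraries, with 141813 and 106004 counts, were the shallowest of the 8 animals of no given arm. Control DNAs had up to 79 called IR sites and up to 745 called JX sites. Among the days listed, the share of called IR sites on chromosome 13 had the largest Pearson's r of 5 relations, 0.245 (permutation test, p 0.0384, adjusted 0.192), and r was 0.151 without the 2 animals farthest from the median.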
